A study of Mus musculus with 11 samples.

How the data were processed

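Gene expression was measured on 11 one-colour Affymetrix arrays of lung RNA from Balb/c mice. The mice were wild type or lacked both Eif4ebp1 and Eif4ebp2, the genes of 2 repressor proteins that bind the cap-binding factor eIF4E and hold back the start of translation. There were 3 arrays of total RNA from each genotype, 2 arrays of polysomal RNA from wild type and 3 arrays of polysomal RNA from knockout lung. Per the labels' protocols, the mice were put on a purified diet at 5 weeks of age. Lung lysate was separated into 10 gradient fractions, and fractions 7 to 10, with 3 or more ribosomes on a transcript, were pooled as the polysomal RNA. Per the labels' protocols, 100 ng of RNA was labelled with biotin in a kit with 2 rounds of amplification. The labels do not say whether each array came from its own mouse, so p-values measure the spread between these arrays, which may be partly technical.

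The deposited values are on a log2 scale, with 1 value per probe set and array. Per the submitters' processing notes they were made with GCRMA, which corrects background, normalizes and summarises probes. Its version is not given in the sources used here, and the log2 scale was read from the values, which ran from 0.73 to 16.7 with array medians between 4.96 and 5.04. The probe set names are RefSeq accessions, so probes had been regrouped by transcript, and the grouping used is not given in the sources used here. Of 26180 probe sets, 15228 matched 1 gene each in the NCBI RefSeq table of assembly GRCm38.p6, giving 14351 genes, and 10952 matched none. Exact repeats of another row made up 7538 probe sets. On 1844 probe sets a total and a polysomal array held an identical value, which points to all 11 arrays having been summarised together. For arrays, the number of arrays limits the precision.

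A probe set was tested where its log2 value was at least 5 on at least 2 of the 11 arrays. This kept 13802 probe sets, of which 5272 had no gene name, and each of 8085 genes was represented by its probe set with the highest mean. limma (version 3.58.1, in R 4.3.3) fitted 1 mean per group over all 11 arrays with lmFit and eBayes, leaving 7 residual degrees of freedom and a prior worth 2.67. There were 5 contrasts: knockout minus wild type in total RNA, the same in polysomal RNA, the difference between these (the interaction), and polysomal minus total RNA within each genotype. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and 0.05 was the threshold. All adjusted p-values for genes come from this limma fit. Differences are given in log2 units with the standard error (SE) of the fit.

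The groups, the tests of the contrasts and of the lists, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. There were 39 lists of pathway members and cell type markers. limma's camera tested the 31 lists with at least 5 tested members, with the correlation between genes preset at 0.01 and, as an alternative, estimated from the data. Adjustment was over the lists of a contrast. Named genes were the 12 with the largest difference in each direction for each genotype contrast (8 for polysomal against total RNA), among genes that passed. Arrays of the groups compared were not to overlap, except for the interaction. From each list, up to 4 members that passed were named by smallest p, or otherwise the smallest p as values. A set of 10 genes was always to be named, of which 7 had a tested probe set. Irf7, Odc1 and Cyp2a5 had none.

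The labels give each array a replicate set letter and do not explain it. Deviations from the group means were compared between arrays with and without the same letter. Alternatives were other filters on low values, moderation with a trend, quantile normalization, equal array medians, blocks for the set letter, another threshold, a minimum fold of 1.5, fits of the groups compared alone, and leaving out each array. Each targeted gene had 1 probe set, so the planned comparison of its probe sets could not be made. Before use, the fit was tested on simulated data with 8085 genes, 7885 of them unchanged in each contrast, and noise drawn separately for each gene. The real data had more changed genes and more probe sets, so the recovery is only a guide to the real fit. In the total RNA contrast, 95.5% of genes changed by 2 log2 units and 32.8% of genes changed by 0.5 were recovered, and in the polysomal contrast 89.4% and 14.9%. For the interaction these shares were 92.4% and 2.99%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.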

Results

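The series compared lungs of Balb/c mice lacking both 4E-BP1 and 4E-BP2 with wild-type lungs, in total RNA and in the RNA bound by several ribosomes. Its title places the work in lung tumour defence at a checkpoint of translation. Comparing both RNA kinds asks which messages changed in amount and which changed in their share on polysomes. There were 3 wild-type and 3 knockout arrays of total RNA, and 2 wild-type and 3 knockout arrays of polysomal RNA. The first principal component held 83.4% of the variance. The median of the 12378 probe sets too dim to test lay at 2.43 to 2.49 log2 on the wild-type total arrays, against 2.34 to 2.39 on the knockout total arrays and 2.30 to 2.35 on the polysomal arrays.

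Eif4ebp2 was lower on every knockout array than on any wild-type array of the same RNA kind. In total RNA it fell by 1.90 log2 units (SE 0.25, n = 3 and 3, limma, Benjamini-Hochberg adjusted p = 0.0016). Its values on the knockout total arrays, 2.61 to 3.26 log2, lie near the floor of 2.34 to 2.39, so the size of this fall is not well measured. In polysomal RNA it fell by 2.07 (SE 0.28, n = 2 wild type and 3 knockout, limma adjusted p = 0.0025). Eif4ebp1 fell by 0.40 in total RNA (SE 0.11, limma adjusted p = 0.033) and by 0.67 in polysomal RNA (SE 0.13, adjusted p = 0.0096), and stayed at 7.92 to 7.94 log2 on the 3 knockout total arrays. Where the Eif4ebp1 probes lie relative to the deleted part is not known here, so this probe set does not check the labels. The total RNA call for Eif4ebp1 was lost when any of 5 arrays was left out. Eif4ebp3, the third member of the family, did not pass in total RNA (-0.15, SE 0.11, limma adjusted p = 0.36) and fell by 0.49 in polysomal RNA (SE 0.12, adjusted p = 0.025), a call lost when any of 4 arrays was left out. The polysomal call for Eif4ebp1 was lost without 1 array.

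**Figure D1:**
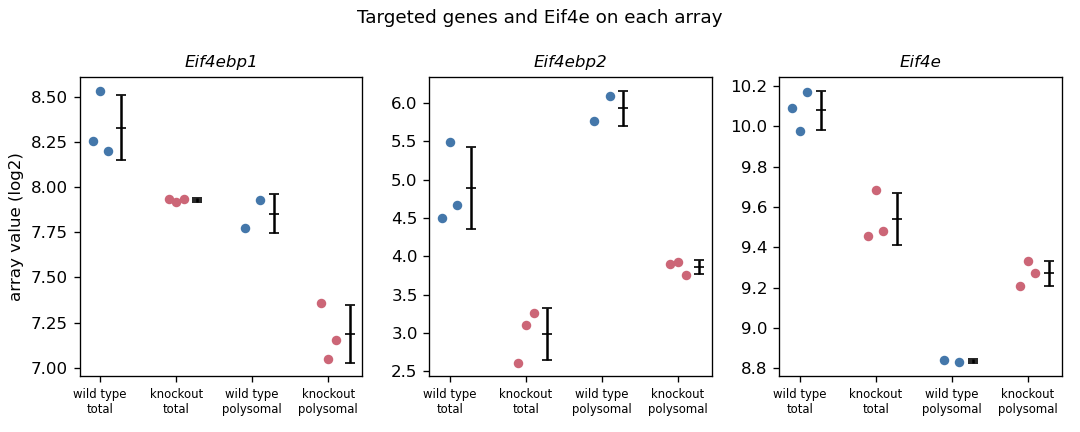
Values of the Eif4ebp1, Eif4ebp2 and Eif4e probe sets on each array (y axis, log2) by group (x axis), with each point an array and the bar beside it the group mean and SD. Eif4ebp2 means were 4.89 and 2.99 in wild-type and knockout total RNA, and Eif4e lay lower in knockout total RNA but higher in knockout polysomal RNA.

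In total RNA, knockout lungs had more RNA of the secreted defence proteins Saa3 and Reg3g, and less of the heat shock gene Hspa1a and the clock gene Cry1. Saa3, an acute phase protein, rose by 2.36 log2 units (SE 0.31, limma adjusted p = 0.0015), and Reg3g, an antimicrobial lectin of airway cells, by 2.72 (SE 0.41, adjusted p = 0.0025). Hspa1a, the inducible HSP70 chaperone, fell by 3.27 (SE 0.67, limma adjusted p = 0.0084), and Cry1, a repressor of the circadian clock, fell by 1.39 (SE 0.19, adjusted p = 0.0017). Cry1 was the 1 of 11 tested clock genes that fell, while 1, Nr1d1, rose and 9 did not pass (camera adjusted p = 0.11). Of 8085 genes tested, 1876 changed, 1393 of them higher and 483 lower, and 368 changed at least 2-fold.

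Several of the largest rises started near the floor in wild-type total RNA. C1qa, a chain of complement C1q made by macrophages, rose by 4.01 (SE 0.22, limma adjusted p = 2.1e-05), from a mean of 3.78 to 7.79 log2. Pef1 rose by 4.00 (SE 0.16), Fam220a by 3.19, Pigs by 2.87, Adamtsl2 by 2.75, Chmp1a by 2.73, Ppp5c by 2.58, Apbb1 by 2.39, Lgals3bp by 2.35 and Zbtb5 by 2.25. In wild-type polysomal RNA C1qa stood at 11.6 and Pef1 at 10.1 log2. Their low wild-type total values therefore cannot be read as a lack of the message, nor their rises as a measured gain in its amount. The other large falls were Dmac2l at -2.19, Gm6377 at -1.93, Ces1g, a carboxylesterase, at -1.62, Hectd2 and Akap14 at -1.47, Iqub at -1.40, Pclo and Zfp959 at -1.39, and Esm1, an endothelial proteoglycan, at -1.37. Calls for Pigs, Adamtsl2, Zbtb5, Dmac2l, Ces1g and Iqub were each lost when 1 of several arrays was left out.

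Of the lists fixed in advance, 6 shifted upward in total RNA and none downward, and without wild-type total replicate 3 there were 7 upward and 3 downward. Of 58 tested nuclear genes of oxidative phosphorylation, 27 rose, none fell and 31 did not pass (camera adjusted p = 5.7e-07, median 0.38, and adjusted p = 0.82 with an estimated correlation). Adjusted over the list alone, 34 rose. Examples were Atp5d (1.05, SE 0.11) and Atp5k (0.86, SE 0.08). Heart muscle markers were at 0.23 to 1.38, with a median of 0.77, and 3 of 8 rose, Myl4 (1.29, SE 0.28), Tnnc1 (1.10, SE 0.24) and Actc1 (0.77, SE 0.19), without a list shift (camera adjusted p = 0.093). The call for Actc1 was lost when any of 3 arrays was left out. Cell cycle genes rose in 11 of 20 cases, 12 adjusted over the list alone, with none lower (adjusted p = 6.1e-05, and adjusted p = 0.30 with an estimated correlation). Among them were the replication helicase subunits Mcm2 (1.26, SE 0.17), Mcm5 (1.10, SE 0.13) and Mcm6 (1.06, SE 0.14), and cyclin D3, Ccnd3 (1.56, SE 0.16).

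Endothelial markers rose in 9 of 13 cases, also 9 adjusted over the list alone (adjusted p = 9.9e-05, and adjusted p = 0.30 with an estimated correlation). They included the receptor kinase Tie1 (1.44, SE 0.14), the junction protein Cldn5 (0.96, SE 0.10) and Ramp2 (1.04, SE 0.12). Of 41 extracellular matrix genes 15 rose, 19 adjusted over the list alone, and 26 did not pass (adjusted p = 0.0015, and adjusted p = 0.82 with an estimated correlation). Mfap4 (1.45, SE 0.19), Mfap5 (1.25, SE 0.17) and Loxl1 (1.10, SE 0.12) were among them. Smooth muscle genes rose in 3 of 5 cases, Tagln, Des and Acta2, and in 4 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.69 with an estimated correlation). Of 9 markers of alveolar type 2 cells, 4 rose, 6 adjusted over the list alone (adjusted p = 0.026, and adjusted p = 0.82 with an estimated correlation). Napsa (1.01, SE 0.12) and Sftpd (0.41, SE 0.09) were examples. The alveolar type 2 call was lost under quantile normalization and without knockout total replicate 3, and the call for Sftpd without 1 array. In wild type, polysomal minus total RNA had medians of 2.04 for endothelial, 1.76 for smooth muscle and 1.21 for matrix genes. It was 0.90 for type 2 and 0.79 for oxidative phosphorylation genes, against 0.22 for all genes. These rises in total RNA thus ran toward the polysomal level, and none of these lists shifted in polysomal RNA. A gain of these messages cannot be told apart from the smaller polysomal difference over all genes described below.

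Cells of other kinds and the initiation machinery gave values in both directions. Among macrophage markers 3 rose, C1qa and Itgax among them, and 4 fell. Those that fell included Siglecf, a marker of alveolar macrophages, at -0.58 (SE 0.12), Ear1 at -0.72 and Chil3 at -0.63. Of 8 neutrophil markers 2 rose, Ltf (1.59, SE 0.19) and Lcn2 (1.40, SE 0.13), and 6 did not pass (camera adjusted p = 0.68). The median of the 8 was 0.52 between the arrays of set A and -1.05 between those of set B, letters the labels do not explain, with 1 or 2 arrays a side and no test. Also higher was Alas2 (1.82, SE 0.30), the heme synthesis enzyme of red cell precursors. Of 35 translation initiation factors and regulators, 6 rose and 2 fell. Eif4e, the cap-binding factor itself, fell by 0.54 (SE 0.09, limma adjusted p = 0.0039), while Eif5a rose by 1.03 (SE 0.13). The list of textbook eIF4E targets did not shift (camera adjusted p = 0.94), with Ccnd3 higher, Mcl1 at -0.32 (SE 0.10) and 10 of 12 members not passing. Of the 22 targets listed only these 12 had a tested probe set, so nothing is known here of the others, Irf7 and Odc1 among them. The call for Mcl1 was lost when any of 8 arrays was left out. Vegfa (0.15, SE 0.11), Ccnd1 (0.25, SE 0.11) and Myc (-0.31, SE 0.27) did not pass. The count of changed genes fell to 964 without knockout total replicate 2 and to 1149 without wild-type total replicate 1. The share of changed genes that were higher, 74.3%, was 60.6% after quantile normalization and 55.2% with equal array medians. It was 37% without a filter on low values, where most of the lower calls were of genes below the filter.

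In polysomal RNA, knockout lungs carried more of the Hells and Cdc6 messages and fewer of the heat shock gene Hspa1a and the carboxylesterase Ces1g. Hells, a chromatin remodeller of dividing cells, rose by 2.71 log2 units (SE 0.28, limma adjusted p = 8.3e-04), and the replication licensing factor Cdc6 by 2.38 (SE 0.23, adjusted p = 7.5e-04). Hspa1a fell by 4.64 (SE 0.74, limma adjusted p = 0.0042) and Ces1g by 3.46 (SE 0.50, adjusted p = 0.0028). In all, 1223 genes changed, 676 higher and 547 lower, at n = 2 wild-type and 3 knockout arrays. The share higher, 55.3%, was 45.1% with equal array medians.

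Other large rises were Slfn4 (3.26, SE 0.84), Tmem184c (2.65), the kinetochore gene Spc25 (2.63), the spindle gene Nusap1 (2.52), Zfp946 (2.24), Dscc1 (2.16), Saa3 (2.07, SE 0.35), Lcorl (2.07), Lipo3 (1.99) and Fignl1 (1.98). A second Lcorl probe set gave 0.53. Other large falls were Srpr (-3.23, SE 0.20), the signal recognition particle receptor, Cd163l1 (-2.86), Usp2 (-2.38), Jchain, the joining chain of secreted antibodies (-2.32, SE 0.55), Acad10 (-2.31), Ctsf (-2.13), Ak8 (-2.08), Cyp4f15 (-2.03) and Irx1 (-2.00). Slfn4 lay near the floor in wild-type polysomal RNA, so the size and rank of its rise are not well measured. The call for Slfn4 was lost when any of 5 arrays was left out, that for Acad10 with any of 7 and that for Jchain with any of 4.

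Of 39 xenobiotic metabolism genes 12 fell, 1 rose and 26 did not pass (camera adjusted p = 5.3e-07, median -0.57, and adjusted p = 0.76 with an estimated correlation). Adjusted over the list alone, 17 fell. Ces1f (-1.99, SE 0.30), Cyp4f15 (-2.03, SE 0.27) and the glutathione transferase Gsta2 (-1.45, SE 0.15) were among them. Cell cycle genes rose in 10 of 20 cases, 13 adjusted over the list alone, with none lower (adjusted p = 7.3e-07, and adjusted p = 0.28 with an estimated correlation). Beside Cdc6 and Nusap1 these included thymidine kinase Tk1 (1.78, SE 0.23) and Mcm6 (1.25, SE 0.15).

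Ciliated cell genes fell in 4 of 10 cases, 6 adjusted over the list alone (adjusted p = 3.6e-04, and adjusted p = 0.44 with an estimated correlation). They were Foxj1, the master regulator of cilia (-1.27, SE 0.17), Dnaic1, Tekt1 and Tekt2. Macrophage markers fell in 5 of 13 cases, also 5 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.76 with an estimated correlation), for example Chil3 (-0.89, SE 0.17), Ear1 (-0.80, SE 0.19) and Itgax (-0.59, SE 0.13). Chil3 and Ear1 fell in total RNA also, whereas Itgax rose there. Of 11 clock genes 5 fell and 1 rose (adjusted p = 0.024, and adjusted p = 0.76 with an estimated correlation), and adjusted over the list alone 8 fell and 2 rose. Ciart (-1.79, SE 0.17) and Cry1 (-1.40, SE 0.21) fell and Clock (1.61, SE 0.24) rose. Calls for Tekt1, Chil3, Ear1 and Itgax were each lost without 1 or 2 of the arrays. The macrophage call was lost without wild-type polysomal replicate 1 and the clock call without wild-type polysomal replicate 2. In wild type, polysomal minus total RNA had medians of 1.615 for xenobiotic, 1.20 for ciliated, 1.16 for macrophage and 0.59 for clock genes. The median of all genes was 0.22. These falls in polysomal RNA thus ran toward the total RNA level. They cannot be told apart from the smaller polysomal difference over all genes described below.

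Eif4e rose by 0.44 in polysomal RNA (SE 0.10, limma adjusted p = 0.022), a call lost when any of 3 arrays was left out. The matrix genes Eln (1.60, SE 0.24) and Mmp14 (1.11, SE 0.11) rose and Dcn fell by 0.55 (SE 0.11), although the matrix list did not shift (adjusted p = 0.19) and the call for Dcn was lost when either of 2 arrays was left out. Of 30 growth factor signalling genes 4 rose, among them Igf1 (1.45, SE 0.30) and Fgf7 (1.18, SE 0.13), 1 fell, the receptor Egfr (-0.84, SE 0.13), and 25 did not pass, without a list shift (adjusted p = 0.48). Interferon response genes rose in 5 of 28 cases without a list shift (adjusted p = 0.073), for example Ifit2 (0.91, SE 0.15). Neither the eIF4E targets (adjusted p = 0.95) nor the cytosolic ribosomal proteins (adjusted p = 0.95) shifted, and Vegfa was at 0.00 (SE 0.13). The count of changed genes was 709 and 619 without wild-type polysomal replicates 1 and 2, 790 and 757 without knockout polysomal replicates 1 and 2, and 682 when fitted on these 5 arrays alone. With a replicate block by set letter within RNA kind it was 776.

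**Figure D2:**
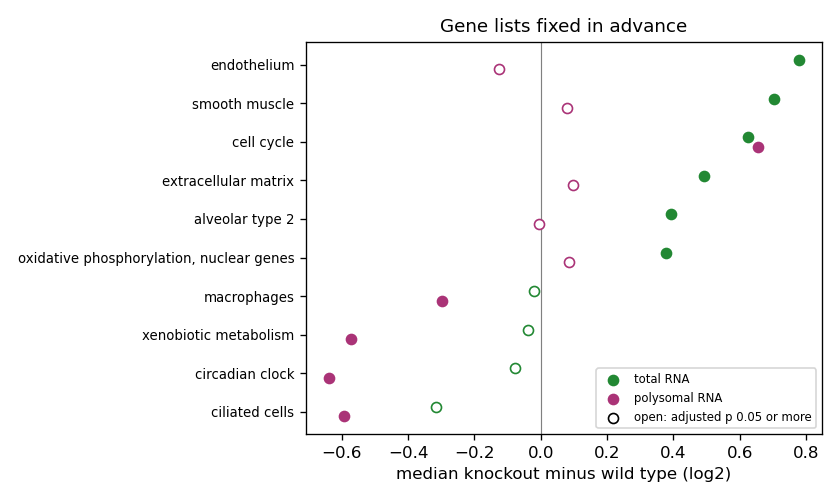
Median knockout minus wild-type difference (x axis, log2) of the tested members of each of the 10 lists that shifted in total RNA, polysomal RNA or the interaction (y axis), with filled points where camera's adjusted p was under 0.05 in that RNA kind. Cell cycle genes shifted upward in both, with medians of 0.62 in total and 0.65 in polysomal RNA (adjusted p = 0.30 and 0.28 with an estimated correlation).

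The interaction asks whether the knockout changed a message on polysomes by a different amount than in total RNA. In knockout lungs 1803 genes differed, 652 with the polysomal change above the total change and 1151 below it. The lowest was C1qa at -4.40 log2 units (SE 0.33, limma adjusted p = 3.3e-04), followed by Pef1 (-4.14), Ppp5c (-2.97), Apbb1 (-2.86), the lysosomal protein Pld3 (-2.73), Lgals3bp (-2.70), Sgo1 (-2.63), Oplah (-2.62), the vascular gene Rasip1 (-2.52), the tight junction gene Cldn3 (-2.50), Asl (-2.44) and Rabac1 (-2.44). The highest was Slfn4 at 4.67 (SE 1.13, limma adjusted p = 0.020), followed by Zfp946 (3.28), Tmem184c (2.95), Lcorl (2.60), Zfp948 (2.44), Tex15 (2.34), Ifi209 (2.33), Fam122b (2.26), the DNA ligase Lig4 (2.25), Ube2v2 (2.19), Hells (2.16) and Pgm2l1 (2.13). Of the 1151 lower genes, 740 had risen in total RNA and 303 had fallen in polysomal RNA, with 53 in both sets. Of the 652 higher genes, 400 had risen in polysomal RNA and 219 had fallen in total RNA, with 85 in both. C1qa at 3.78 and Pef1 at 3.48 log2 in wild-type total RNA and Slfn4 at 2.54 in wild-type polysomal RNA lay near the floor, so the sizes and order of these differences are not well measured. Over all genes, polysomal minus total RNA in knockout had a slope of 0.684 on that in wild type. Messages high on polysomes in wild type thus tend to lie below 0 here, such as C1qa, Pef1, Lgals3bp, Rabac1 and Pld3. Those low on polysomes tend to lie above 0, such as Slfn4, Tmem184c, Lcorl and Zfp946. The call for Asl was lost when any of 8 arrays was left out, for Tex15 with any of 4, for Oplah and Lgals3bp with any of 3, for Apbb1 with either of 2, and for Slfn4 and Ifi209 with 1.

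Endothelial markers were lower by this measure in 9 of 13 cases, 10 adjusted over the list alone (camera adjusted p = 1.4e-04, and adjusted p = 0.45 with an estimated correlation). Tie1 (-1.59, SE 0.20), Ramp2 (-1.17, SE 0.18), Esam (-0.97, SE 0.14) and the transcription factor Sox17 (-0.88, SE 0.12) were among them. In polysomal RNA itself the endothelial list did not shift (camera adjusted p = 0.60), with 1 marker higher, 1 lower and 11 not passing. Its median was 0.78 in total RNA and -0.13 in polysomal RNA, so the lower interaction mainly carried the rise in total RNA. No other list passed in the interaction, although 13 of 58 oxidative phosphorylation genes were lower and none higher (adjusted p = 0.077). Eif4e was 0.98 above its total RNA change on polysomes (SE 0.14, limma adjusted p = 0.0038), and Pdcd4, an inhibitor of eIF4A, was 0.93 above (SE 0.16). In wild type Eif4e lay at 9.98 to 10.17 log2 in total RNA and at 8.83 to 8.84 in polysomal RNA. The smaller polysomal difference over all genes in knockout would by itself give such a message an interaction above 0. How far the Eif4e value exceeds that was not tested. Textbook eIF4E targets did not shift (adjusted p = 0.95), with Ccnd3 at -1.61 (SE 0.24) and Nbn at 1.24 (SE 0.37), a call lost when any of 8 arrays was left out. Without wild-type polysomal replicate 2 the count was 1068, without wild-type total replicate 1 it was 1115 and without knockout total replicate 2 it was 1134.

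Across the 8085 genes, the knockout differences in total and polysomal RNA were nearly uncorrelated (Pearson r = 0.087, Spearman rho = 0.0085), and genes are not independent replicates. The arrays behind the differences were not shared. Genes higher in both RNA kinds numbered 99 against 116.5 for independent lists, and genes lower in both numbered 71 against 32.7. Genes lower in total and higher in polysomal RNA numbered 85 against 40.4, and the reverse 53 against 94.3. Saa3, Cdc6, Alas2 and Mcm6 were higher in both, and Hspa1a and Cry1 lower in both.

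Polysomal and total RNA differed widely within each genotype. In wild-type lung 5853 genes differed, 3595 higher and 2258 lower on polysomes, and in knockout lung 5275, with 3195 higher and 2080 lower. In wild type the largest excess on polysomes was that of the adhesion molecule Bcam (7.81, SE 0.14), with C1qa (7.80), Pef1 (6.63), Sppl2a (6.58), the cathepsin Ctsf (6.51), Lgals3bp (6.51), Rabac1 (6.43) and Pld3 (6.32). The largest deficits were those of Slfn4 (-8.30, SE 0.84), Tmem184c (-5.67), the cytokine Tslp (-5.43), Znrf2 (-5.14), Lcorl (-4.80), Zfp677 (-4.74), Zfp946 (-4.45) and Doc2a (-4.42). Many of these genes lay near the floor in one RNA kind, Bcam at 1.75 log2 in total RNA for example, so these sizes and their order are not well measured, in wild type or in knockout. A message bright on polysomes should also be present in total RNA, so these differences cannot be read as shares on polysomes alone. A difference in how the RNA kinds were prepared or read cannot be told apart from them. In knockout lung Bcam (7.58, SE 0.12), Sppl2a (6.79), Spr (4.88), H2-DMb1 (4.67), Cirbp (4.65), Slc29a1 (4.64), Ptprf (4.57) and Ltbp4 (4.53) led, and Tslp (-4.50), Fam149a (-3.81), Snx21 (-3.74), Slfn4 (-3.63), Rpl37a (-3.60), Znrf2 (-3.59), Myoz2 (-3.53) and Ankrd40 (-3.44) trailed.

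Of the lists, 7 differed between polysomal and total RNA in wild type and 6 in knockout, against 3 and 6 with a replicate block by set letter within RNA kind. Of 78 cytosolic ribosomal protein genes 20 had a tested probe set. They were lower on polysomes in 13 of 20 cases and higher in 4 in wild type, also 13 lower adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.75 with an estimated correlation) and lower in 16 of 20 and higher in 1 in knockout, also 16 lower adjusted over the list alone (adjusted p = 3.2e-05, and adjusted p = 0.64 with an estimated correlation). Endothelial markers were higher in 13 of 13 cases in wild type, also 13 adjusted over the list alone (adjusted p = 6.3e-04, and adjusted p = 0.62 with an estimated correlation), and in 11 in knockout, also 11 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.64 with an estimated correlation). Extracellular matrix genes were higher in 30 of 41 cases in either genotype (adjusted p = 0.0027 in wild type and 2.2e-04 in knockout, and adjusted p = 0.75 and 0.79 with an estimated correlation). Xenobiotic metabolism genes were higher in 30 of 39 cases in wild type and 27 in knockout (adjusted p = 0.0023 and 0.0044, and adjusted p = 0.75 and 0.79 with an estimated correlation). A replicate block by set letter within RNA kind ended the matrix call in wild type and the xenobiotic call in knockout. The size of the difference between polysomal and total RNA was smaller in knockout lung. The SD over genes of polysomal minus total RNA was 1.48 log2 units in wild type and 1.09 in knockout, a ratio of 0.737, with r = 0.927 across genes. Among 200 relabelings of the arrays within RNA kind the labelled grouping had the lowest ratio, and the two-sided exact permutation test gave p = 0.005, the smallest these can give. The ratio and its permutation test were not among the tests fixed in advance. The median of all genes in this comparison for wild type, 0.22, was 0.059 after quantile normalization.

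**Figure D3:**
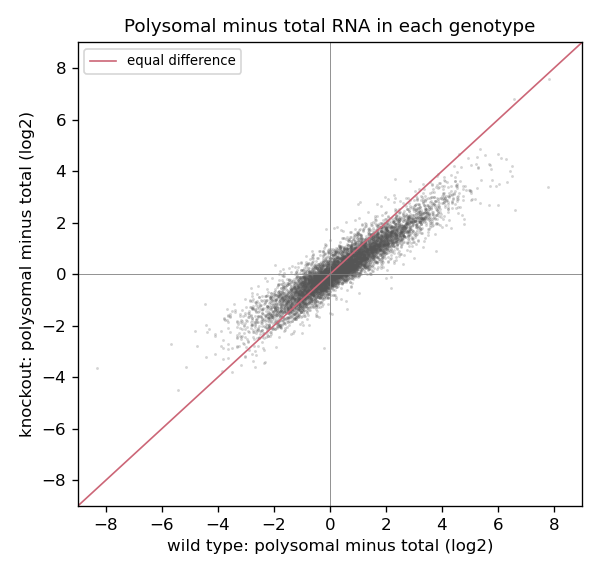
Polysomal minus total RNA (log2) of each of 8085 genes in wild type (x axis) and knockout (y axis), with the line of equal difference. The cloud is flatter than the line, with SDs of 1.09 against 1.48.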

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

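Tests of the smaller polysomal difference, the clock genes and the neighbours of the targeted genes, and the count of splits for the lists of polysomal against total RNA, were chosen after the results were seen, as was leaving out each array for the genes that differed between RNA kinds. Of 44 genes named for a large knockout difference in total or polysomal RNA, 22 differed between the RNA kinds by limma's interaction test with Benjamini-Hochberg adjustment, against 22.3% of all 8085 genes. Picking genes by a large difference in one RNA kind itself raises this number. With 1 of the 11 arrays left out at a time, 14 of the 22 kept their call throughout. Calls were lost with any of 8 arrays for Nusap1, Fignl1 and Cd163l1, any of 6 for Cdc6, any of 3 for Lgals3bp, either of 2 for Apbb1, and 1 for Slfn4 and Chmp1a. The value given is the polysomal difference minus the total difference, in log2 units. It was -4.40 for C1qa, -4.14 for Pef1, -2.20 for Chmp1a, -2.97 for Ppp5c, -2.86 for Apbb1 and -2.70 for Lgals3bp, all of which had risen in total RNA. For genes that fell in polysomal RNA it was -1.87 for Srpr, -2.15 for Cd163l1, -2.29 for Ctsf, -1.59 for Ak8, -1.74 for Cyp4f15 and -1.45 for Irx1. It was 2.09 for Zfp959. Genes that rose in polysomal RNA gave 4.67 for Slfn4, 2.16 for Hells, 2.95 for Tmem184c, 1.68 for Nusap1, 1.12 for Cdc6, 3.28 for Zfp946, 2.60 for Lcorl, 2.12 for Lipo3 and 1.30 for Fignl1. The endothelial list had a median of -0.829, beside medians of 0.78 in total RNA and -0.13 in polysomal RNA.

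The difference between polysomal and total RNA was smaller in knockout lung, with a ratio of SDs of 0.737, and the total RNA change of many genes ran toward their polysomal level. Noise of single arrays shared between the differences compared does not account for this. With separate arrays on each side, the knockout change in total RNA correlated at 0.339 or more with polysomal minus total RNA averaged over both genotypes. In polysomal RNA the correlation was -0.327 to -0.202, also the direction of a smaller difference. The labels do not say whether arrays share a mouse, so noise common to several arrays is not covered. A single deviating array does not account for the smaller difference, because the ratio stayed at or below 0.752 with any 1 of the 11 arrays left out. Genes dim on all arrays do not account for it either, since the ratio was 0.733 among the 4042 genes with the brighter mean over the 11 arrays. Genes near the floor in only 1 RNA kind can be among these, so the test cannot exclude an effect of array background there. A difference in RNA quality between genotypes follows the groups and stays open, as does an effect of losing 4E-BP1 and 4E-BP2. A difference in the gradient stays open for the polysomal arrays only, since only polysomal RNA was pooled from its fractions. None of these was tested.

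Of 11 clock genes, 5 were lower and 1, Clock, higher in knockout polysomal RNA, a list call lost with an estimated correlation (adjusted p = 0.76) and without wild-type polysomal replicate 2. A candidate explanation is another time of day at collection, which would order the changes by when each gene peaks. Spearman's rho of the total RNA change with the order of the peaks was -0.607 over 11 genes (permutation p = 0.0522, Benjamini-Hochberg adjusted p = 0.0522 over both RNA kinds), and in polysomal RNA it was -0.713 (permutation p = 0.0162, adjusted p = 0.0325). The permutation shuffled genes, which are not independent, so its p does not measure the spread between arrays. The order was coarse and placed a daily cycle on a line, and the total RNA test missed its threshold. The time of collection and the genotype therefore cannot be told apart.

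Of the 50 tested genes nearest Eif4ebp2 by gene order in GRCm38.p6, 4 changed the same way in both RNA kinds (Nus1, Man1a, Fam241b and Pbld2), as did 0 of 50 beside Eif4ebp1 and 2.05% of other genes. Alleles of a donor strain linked to the targeted genes could give such a cluster. The two-sided Fisher's exact test over both sets of neighbours gave p = 0.154, too few genes to decide, and the explanation stays open.

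Splits of the 6 total RNA arrays into 3 and 3 number 10, too few for a share under 0.05. The labelled split gave 1876 changed genes and was the 1 split to give that many, with 0 as the highest of the others, and for polysomal against total RNA in knockout 1 of 10 splits gave as many as the 5275 observed, again with 0 as the highest other. For the lists, 3 of the 10 splits of the total RNA arrays gave at least the 6 observed shifts and the highest other gave 8. For polysomal against total RNA in knockout 5 of 10 splits gave at least the 6 observed and the highest other gave 12. List calls with the preset correlation therefore also appear in groupings that mix the genotypes, in total RNA, or the RNA kinds, in knockout.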

How the results depend on the processing

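The alternatives with identical rows dropped, with equal array medians for lists and named genes, and for the ratio of SDs were chosen after seeing the data. No named gene or list call changed direction under any alternative run for it. Without a filter on low values 4216 genes changed in total RNA and 10360 between polysomal and total RNA in wild type, where 37.4% of the changed genes were then higher against 61.4% with the filter. Of the 2655 lower calls in total RNA, 2067 lay below the filter with a median of -0.10 log2, beside array floors of 2.43 to 2.49 log2 in wild type and 2.34 to 2.39 in knockout. A minimum of 1.5-fold left 1105 genes in total and 803 in polysomal RNA, adjusted p under 0.10 gave 1906 in polysomal RNA, and the 5 polysomal arrays fitted alone gave 682. Residuals gave no sign of pairing by set letter in total RNA and cannot decide it in polysomal RNA. In total RNA, arrays of both genotypes correlated at a median of 0.0021 with the same letter (4 pairs) and 0.00235 with another letter. In polysomal RNA the medians were 0.089 (2 pairs of equal value) and -0.051. With a replicate block by letter within RNA kind, the counts were 776 in polysomal RNA and 1178 for the interaction, and list shifts numbered 10 in polysomal RNA, 4 in the interaction and 3 for polysomal against total RNA in wild type. This block ended the list calls of oxidative phosphorylation, lipid synthesis, extracellular matrix and fibroblasts for polysomal against total RNA in wild type and of xenobiotic metabolism in knockout, ended 67 named gene calls and added 3, and the cause was not tested. In a fit of all 11 arrays with 1 mean for each group and letter, which leaves 2 residual degrees of freedom, 0 genes changed in total RNA by limma within set A (1 knockout and 2 wild-type arrays, 2409 at an unadjusted p under 0.05) and 981 within set B (2 and 1). The lone array is assumed to vary like the others. With an estimated correlation 0 lists shifted in each of the 5 contrasts, and equal array medians gave 2 in the interaction. Quantile normalization ended 4 of 25 list calls and 12 named gene calls, and equal array medians ended 10. The share of interaction genes above 0, 36.2%, was 43.3% after quantile normalization and 42.9% with equal array medians.

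Leaving out 1 array gave 964 to 2163 changed genes in total RNA, lowest without knockout total replicate 2 and highest without wild-type total replicate 3, 619 to 1644 in polysomal RNA and 1068 to 2087 in the interaction. For polysomal against total RNA it gave 5297 to 5865 in wild type and 4779 to 5492 in knockout. A group left with 1 array is assumed to vary like the others. List shifts ran from 5 to 10 in total RNA and from 1 to 4 in the interaction. Of the named genes that passed, 90 of 119 kept their call whichever array was left out in total RNA, 50 of 95 in polysomal RNA and 67 of 109 in the interaction. The ratio of SDs ranged from 0.722 to 0.752, and r between total and polysomal differences from 0.028 to 0.14. Signal over background limits the size of changes that start near the floor, such as that of C1qa from 3.78 log2 in wild-type total RNA.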

Other observations

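Some members of lists fixed in advance changed although their lists did not shift or could not be tested, and no test of a gene or list here was chosen after seeing the data. In total RNA the alveolar type 1 genes Aqp5 (0.79, SE 0.09), Gprc5a (1.09, SE 0.19) and Ager (0.41, SE 0.07) rose, 3 of 8 tested members with none lower (camera adjusted p = 0.26). Among 19 targets of p53 and cell cycle inhibitors 5 rose and 3 fell in total RNA (camera adjusted p = 0.85). Phlda3 (2.13, SE 0.27) and Bax (1.35, SE 0.21), both known to be induced by p53, rose, while Perp fell by 0.53 (SE 0.12). The inhibitors Cdkn2c (0.94, SE 0.22) and Cdkn2b (0.50, SE 0.12) rose in total RNA and also in polysomal RNA (1.12, SE 0.25, and 0.71, SE 0.14), although the calls for Cdkn2c in either RNA kind and for Cdkn2b in polysomal RNA were lost without 1 array.

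Heat shock genes other than Hspa1a also fell in polysomal RNA: Dnajb1 by 1.498 (SE 0.27), Hsph1 by 1.59 (SE 0.36) and Hspb1 by 1.14 (SE 0.28). With Hspa1a these were the 4 of 23 immediate early and heat shock genes that fell there, with none higher (camera adjusted p = 0.090). In total RNA only Hspa1a fell among these 23, while 3 rose, the heat shock gene Hsp90ab1, Ier2 and Zfp36. The other 19 did not pass there (camera adjusted p = 0.64). The call for Dnajb1 was lost without 1 array, for Hsph1 with either of 2 left out and for Hspb1 with any of 3. The T and natural killer cell genes Ccl5 (1.93, SE 0.50) and Klrd1 (1.18, SE 0.27) rose, 2 of 10 tested members with none lower (camera adjusted p = 0.073), and each call was lost when any of 3 or 4 arrays was left out. Thbs1, an inhibitor of angiogenesis, fell by 1.16 (SE 0.14) and Angptl4 by 0.68 (SE 0.17), among 33 angiogenesis genes of which 3 fell and none rose in polysomal RNA (camera adjusted p = 0.78), and the call for Angptl4 was lost when any of 3 arrays was left out. The noncoding RNA Tug1 rose by 0.76 in polysomal RNA (SE 0.10, limma adjusted p = 0.0018), and its list, with 2 tested members, had no list test.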
